A study of Sus scrofa with 11 samples.

How the data were processed

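RNA of 5 cell populations of the pig was hybridised to custom Agilent porcine arrays, 1 sample per array with Cy3 as the only dye: CD163high and CD163low SIRP-positive skin cells (2 arrays each), Langerhans cells (2), blood monocytes (2) and blood B lymphocytes (3). Per the labels' protocols, skin biopsies of Large White pigs were split into dermis and epidermis with dispase, cultured overnight, the dermis digested with collagenase, and cells sorted on CD172a, CD163 and MHC class II. RNA of different animals was mixed where too little was obtained, per the same protocols. How the blood cells were prepared is not given in the sources used here.

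The deposited table holds log2 intensities, with 1 value for each of 43435 features on each of 11 arrays and no missing value. Limma is named in the submitters' processing notes. The values were quantile normalised by the authors, as the values themselves show: the sorted columns of the table differ by at most 0.0409, and the median of every column is 5.26. The feature extraction, the background correction, the treatment of control and replicate spots and any filter are not given in the sources used here, and neither are slides or dates, so no batch could be tested. Feature numbers run up to 45220, and 1785 numbers are not listed. Values run from −2.61 to 18.71. The scale is log2 by its range, the values are not centred per feature, and no scanner file was used to check it.

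Features are identified by number only, and 0 of the numbers match an identifier of the gene tables used here. No gene is therefore named. The planned lists of marker and pathway genes, and the tests on them, were not run, nor was the alternative that averages the probes of a gene. Quantile normalisation of a table ranks signals within an array, so a population with a different amount of total transcript, or with many features moving one way, would be forced to the same distribution. It also leaves the dim end of the scale to the ordering of near-background signals.

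Tests were made with limma 3.58.1 in R 4.3.3 on the values as deposited: a mean per population over all 11 arrays (lmFit), contrasts, and moderated tests (eBayes, two-sided), with 6 residual and 4.35 prior degrees of freedom. The 5 populations thus share one estimate of the spread per feature. P-values were adjusted with Benjamini-Hochberg over all features of a contrast, at 0.05. The 5 planned contrasts were CD163high against CD163low cells, Langerhans cells against each of these, the mean of the 3 skin populations against monocytes, and B cells against monocytes. Standard errors are those of the moderated fit. A feature specific to a population had to pass against each of the other 4, with a log2 difference of at least 1. Correlations between populations are the mean of Pearson's r over pairs of arrays after centring each feature on the mean of the 5 population means. They describe these arrays and carry no test. Design, tests and alternatives were chosen before the data were examined, except for the comparisons of each skin population with monocytes and for what is named as added.

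The rule for the features named was the 2 largest differences in each direction per contrast. Where one of these did not pass the threshold, the largest that passed without overlap between arrays is given too, as a choice made after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

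The fit was tested on simulated normal values with the mean and fitted SD of each of the 43435 features, equal in all populations, of which 200 were changed. The higher noise of the Langerhans arrays was not simulated. For CD163high against CD163low cells it recovered 2.99% of changes of 1 on the log2 scale, 56.7% of changes of 2 and 95.5% of changes of 3, with 6 false calls. For the skin against monocytes it recovered 10.4%, 89.6% and 97.0% with 8 false calls. For features specific to monocytes it recovered 0%, 40.3% and 89.4% with 0 false calls. Changes of 1 on the log2 scale were thus mostly missed in simulation. With 200 changed features, fewer than passed in any contrast, the adjusted threshold was stricter than in the data. The recovered shares and false calls therefore do not carry over to the contrasts.

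Alternatives were a repeat of quantile normalisation, scaling to the 75th percentile, leaving out the dimmest 25% or 50% of features, the replicate number as a block, array weights, a prior trend with intensity, only the arrays compared, a minimum log2 difference of 1, no minimum difference for specific features, Spearman's correlation, and leaving out each array in turn.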

Results

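Gene expression was measured in 5 sorted cell populations of the pig on 11 one-colour Agilent arrays. Skin cells positive for SIRP (CD172a, a receptor of myeloid cells) were sorted into a CD163high population (2 arrays) and a CD163low population (2 arrays). CD163 is the haemoglobin scavenger receptor of macrophages and related cells. Langerhans cells, the dendritic cells of the epidermis, made up the third skin population (2 arrays). Monocytes (2 arrays) and B lymphocytes (3 arrays) came from peripheral blood. The labels call both SIRP-positive populations dendritic cells, while the sorting protocol uses the word CD163high for a macrophage gate with low MHC class II and CD163pos for a dendritic gate with high MHC class II. Which of these gates the CD163high arrays hold is not stated.

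The table gave a log2 intensity for 43435 numbered array features on every array, with no gene name and no detection flag, so features are identified here by their number. A feature at a log2 level below 4.57, where 40% of the features had their mean, is in the dim part of the scale, and a difference against such a level is not an exact fold. The number of arrays limits the precision. The spread between replicate arrays, pooled over features, was 0.431 (SD, log2) for CD163high cells, 0.447 for CD163low cells, 0.420 for monocytes and 0.446 for B cells, and it was highest for Langerhans cells at 0.598. Replicate arrays correlated at r = 0.963 (Langerhans cells) to 0.983 (B cells), and arrays of different populations at 0.868 to 0.959, across features, which are not independent replicates. Nothing states that replicates of a population came from separate animals, and RNA of several animals was mixed where amounts were low, so the p-values measure the spread between these samples only.

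The arrays were first set against each other to ask which populations resembled which, after each feature was centred on its mean over the 5 populations. CD163low and Langerhans cells had the highest mean r of any 2 populations, at 0.247 ± 0.0461 (SD over 4 pairs of arrays, range 0.193 to 0.298). CD163low cells and monocytes had the lowest, −0.480 ± 0.0228, but not in every setting. Without Langerhans replicate 1 or 2, Langerhans cells and monocytes were lower (−0.485 against −0.465, and −0.496 against −0.458). Without CD163high replicate 1 or B cell replicate 3, B cells and CD163high cells were lower (−0.497 against −0.478, and −0.463 against −0.461). CD163high cells gave 0.0852 ± 0.119 with CD163low cells, −0.104 ± 0.0713 with monocytes and −0.225 ± 0.0499 with Langerhans cells. Langerhans cells and monocytes gave −0.433 ± 0.0275. Of all populations B cells had the highest r with monocytes, 0.0371 ± 0.0526 (6 pairs of arrays, −0.0180 to 0.126), above that of CD163high cells, and they gave −0.436 ± 0.0510 with CD163high, −0.409 ± 0.0212 with CD163low and −0.300 ± 0.0362 with Langerhans cells. The B cell values were added after the data were seen. Centring pushes r between populations below 0, so at most the order of the values is read here. That order also depends on the populations included, of which 3 are from skin. It was not the same by the root mean square log2 difference given under other observations, also added later. There CD163high cells were nearer to monocytes (1.04) than B cells were (1.11). CD163low cells and monocytes (1.16) were not the farthest apart, as CD163high and B cells gave 1.34. The value for CD163high and CD163low cells was −0.0252 without CD163high replicate 2, and that for CD163high cells and monocytes was −0.168 without CD163high replicate 1. On all arrays, Spearman's correlation was 0.00988 for CD163high and CD163low cells and −0.0448 for CD163high cells and monocytes. Replicates of one population gave r between 0.529 (Langerhans cells) and 0.845 (B cells). In average-linkage clustering every array joined its own population first. CD163low and Langerhans cells then joined each other, B cells joined monocytes, and CD163high cells joined the other skin populations.

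**Figure D1:**
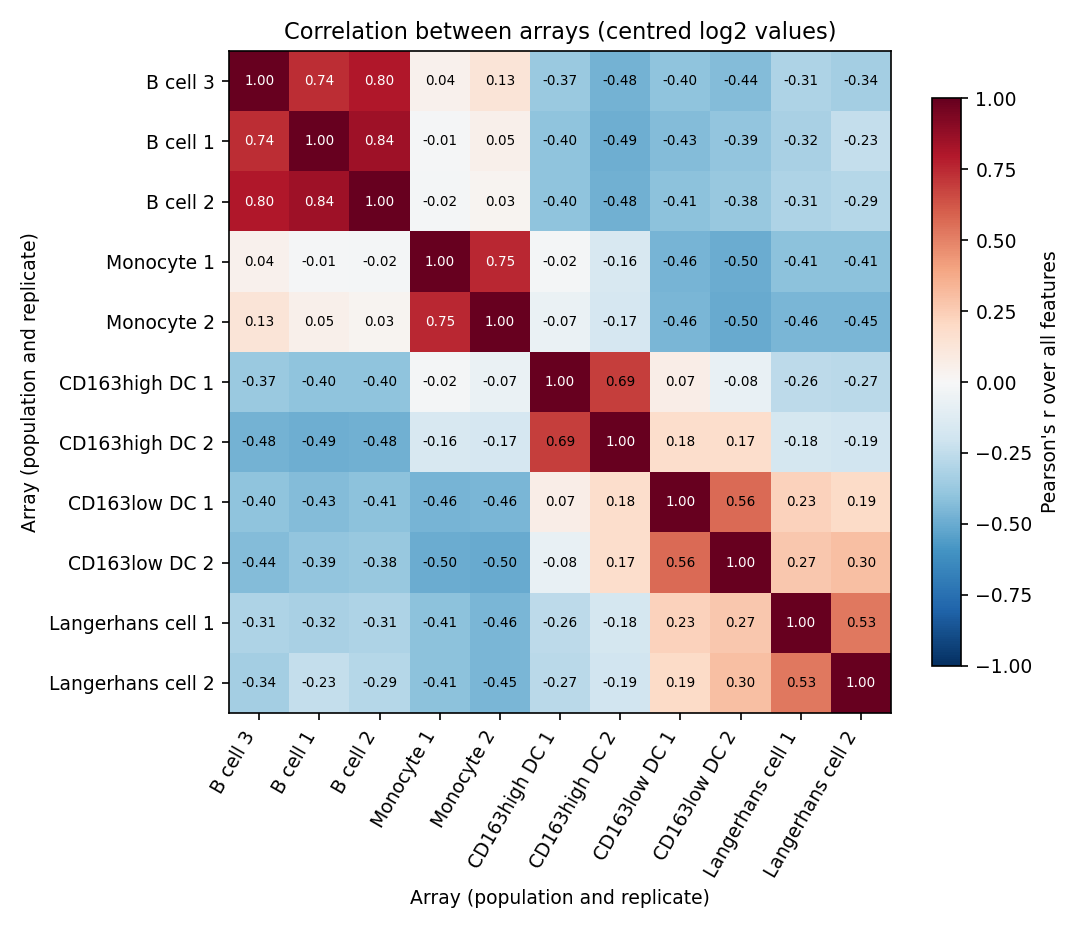
Pearson's r between the centred log2 values of all pairs of the 11 arrays over all features (both axes: population and replicate number, in the order of average-linkage clustering; colour from −1 to 1). The CD163low and Langerhans arrays give r of 0.19 to 0.30 with each other, and with monocytes the CD163low arrays give −0.50 to −0.46, the Langerhans arrays −0.46 to −0.41 and the CD163high arrays −0.17 to −0.02.

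The comparison of CD163high with CD163low cells asks which transcripts go with the CD163 level among SIRP-positive skin cells. Of the 43435 features, 3974 (9.15%) differed at an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2148 higher and 1826 lower in CD163high cells. The difference was 3 or more on the log2 scale for 354 of the higher and 243 of the lower features. Feature 1974 rose most, by 7.53 ± 0.54 (log2, SE, adjusted p = 0.000391), with a mean level of 14.96 ± 0.07 (SD, n = 2) in CD163high cells and 7.44 ± 0.24 (n = 2) in CD163low cells. The same feature was at 3.26 in Langerhans cells and 3.88 in monocytes. Feature 18189 had the next largest rise, by 7.37 ± 0.45 (adjusted p = 0.000236), and was at 4.43 in Langerhans cells and 3.90 in monocytes. The largest differences in the other direction, of feature 24971 (−7.22 ± 2.22, adjusted p = 0.0758) and feature 38944 (−5.68 ± 2.68, adjusted p = 0.269), did not pass. In both, the CD163low arrays were far apart, with an SD of 7.01 and 8.51. Without CD163low replicate 1 the differences were −12.18 and −11.70 (adjusted p = 4.65e-05 for each), and without replicate 2 they were −2.26 and 0.34. Feature 24971 also passed with the dimmest 50% of features left out (adjusted p = 0.0495). Among features that passed, feature 12235 (−5.06 ± 1.06, adjusted p = 0.0148) and feature 9269 (−4.95 ± 0.92, adjusted p = 0.00824) fell most, and these were chosen after the values were seen. Both rest on CD163high arrays that were apart (SD 2.99 and 2.14). Without CD163high replicate 1 they gave −2.95 and −3.44 and did not pass (adjusted p = 0.053 and 0.0621). Feature 12235 also did not pass without CD163low replicate 1 (adjusted p = 0.0604), without CD163low replicate 2 (0.0939) or with only the 4 arrays compared in the fit (0.0596).

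The arrays of the populations did not overlap in 51.6% of all features, against 33.3% by chance. The count of 3974 was 1217 without CD163high replicate 1, 1528 without CD163low replicate 2 and 2573 without CD163low replicate 1, each of which leaves a population with 1 array.

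Langerhans cells and CD163low cells, an epidermal and a dermal population, differed in 1742 features (4.01%), the fewest of the 11 contrasts fitted. Of these, 1056 were lower and 686 higher in Langerhans cells, and the difference was 3 or more on the log2 scale for 290 of the lower and 83 of the higher features. Feature 41999 fell by 8.15 on the log2 scale (SE 1.01, adjusted p = 0.00193) and feature 31109 fell by 7.95 (SE 0.96, adjusted p = 0.00171). Feature 41999 lay at 3.07 ± 1.18 (SD, n = 2) in Langerhans cells, 11.22 ± 0.66 in CD163low cells, 13.54 ± 0.55 in monocytes and 16.63 ± 0.52 in CD163high cells. Feature 31109 followed the same order, from 4.75 in Langerhans cells through 12.69 and 14.75 to 17.73 in CD163high cells. Whether both features measure one gene is not known here. In the other direction the largest difference, of feature 35916 (6.26 ± 2.73, adjusted p = 0.257), did not pass. Its Langerhans arrays were far apart (SD 8.74), and the difference was 12.43 without Langerhans replicate 2 (adjusted p = 2.11e-06) and 0.08 without Langerhans replicate 1. Feature 18939 rose by 6.21 ± 0.50 (adjusted p = 0.000185), to 12.90 in Langerhans cells against 6.69 in CD163low cells, and was at 9.96 in monocytes. Feature 6835, chosen after the values were seen, rose by 5.41 ± 0.54 (adjusted p = 0.000586) and was below 4.57 in every other population.

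With only the 4 arrays compared in the fit, 404 features passed (91 higher, 313 lower), and with array weights 766 passed. The count was 2717 without Langerhans replicate 2, 795 without CD163low replicate 1 and 768 without CD163low replicate 2.

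Between Langerhans cells and CD163high cells, the skin populations with the lowest r, 6811 features (15.7%) differed, 3306 higher and 3505 lower in Langerhans cells. This balance is not firm, as 3554 were higher and 3203 lower with the dimmest 50% of features left out, and 3931 and 3871 without Langerhans replicate 2. Differences of 3 or more on the log2 scale numbered 389 among the higher and 945 among the lower features. Feature 41999 fell by 13.56 on the log2 scale (SE 1.01, adjusted p = 2.4e-05) and feature 31109 fell by 12.98 (SE 0.96, adjusted p = 2.38e-05). Feature 9854 rose by 7.52 ± 0.71 (adjusted p = 8.58e-05), from 4.64 ± 0.02 (SD, n = 2) in CD163high cells to 12.16 ± 0.79 in Langerhans cells, with CD163low cells at 7.33 ± 1.93. Feature 20991 rose by 7.23 ± 0.91 (adjusted p = 0.000455). It was at 14.43 in Langerhans cells and 11.98 in CD163low cells, and its CD163high arrays were apart (SD 2.82). With only the 4 arrays compared in the fit the count was 3974, with array weights 4532, and without CD163high replicate 1 it was 3666.

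**Figure D2:**
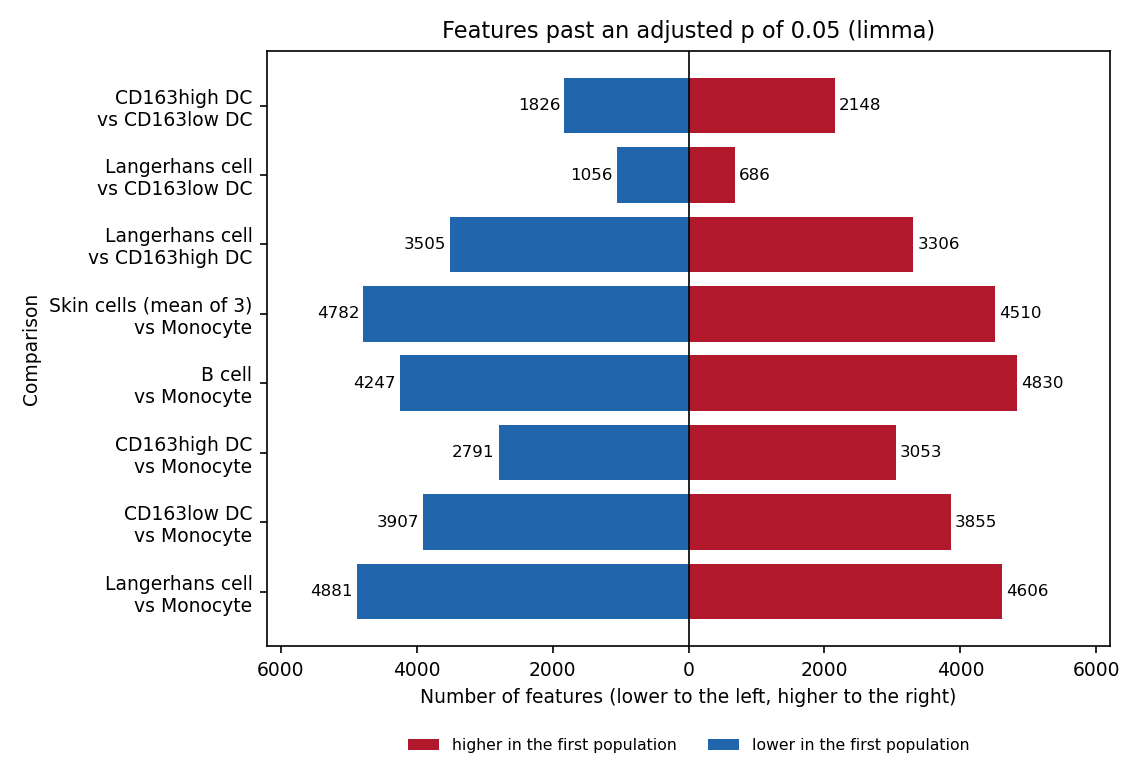
Number of features past an adjusted p of 0.05 in limma (horizontal axis, lower in the first population to the left and higher to the right) for 8 comparisons of populations (vertical axis). Of these 8, Langerhans cells against CD163low cells gave the fewest, with 686 higher and 1056 lower.

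The 3 skin populations together were set against monocytes, a blood cell of the myeloid lineage, to ask what separates skin cells from a circulating relative. Tissue goes with this contrast, and so do the digestion and overnight culture that the protocol describes for skin. The mean of the 3 skin populations differed from monocytes in 9292 features (21.4%), 4510 higher and 4782 lower in the skin. The balance is not firm, as 3761 were higher and 3684 lower with a minimum log2 difference of 1. Differences of 3 or more on the log2 scale numbered 741 among the higher and 538 among the lower features. The skin and monocyte arrays did not overlap in 26.0% of all features (11279), against 7.14% if all arrays were interchangeable. As the 6 skin arrays are 3 populations that differ from each other, 7.14% is too low a reference, and no excess is read from it. The skin and monocyte arrays overlapped in part of the features that passed, as 7430 of the 9292 were without overlap. Feature 3251 rose most, by 10.60 ± 0.37 (SE, adjusted p = 1.81e-07): it was at 3.65 ± 0.17 (SD, n = 2) in monocytes and 3.18 ± 0.82 (n = 3) in B cells, against 13.81 ± 0.22, 13.70 ± 0.04 and 15.22 ± 0.38 (n = 2 each) in CD163high, CD163low and Langerhans cells. Feature 2814 rose by 10.27 ± 0.39 (adjusted p = 3e-07), with a lower level in CD163high cells (11.40 ± 1.19) than in CD163low (14.93 ± 0.35) and Langerhans cells (14.68 ± 0.51). Feature 35454 fell by 10.29 on the log2 scale (SE 0.81, adjusted p = 1.58e-05) and feature 17595 fell by 9.13 (SE 0.77, adjusted p = 2.33e-05). Feature 35454 was at 14.37 ± 0.41 in monocytes and between 3.70 and 4.78 in the skin populations. Both had a wide spread in B cells (SD 1.94 and 1.90, n = 3).

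Taken one by one, CD163high cells differed from monocytes in 5844 features (3053 higher, 2791 lower), CD163low cells in 7762 (3855 higher, 3907 lower) and Langerhans cells in 9487 (4606 higher, 4881 lower). These 3 counts were added after the data were seen and share the monocyte arrays. The differences between the counts were not themselves tested. For CD163low cells the balance of higher and lower features is not firm, as it turned in 9 of 20 settings. With a minimum log2 difference of 1, 3680 were higher and 3646 lower. For CD163high and Langerhans cells it turned in 1 setting each. The pooled count of 9292 was 5407 and 5382 without monocyte replicate 1 and 2. Leaving out either array of either side gave 3416 to 3647 for CD163high cells, and the lowest values were 4636 for CD163low cells (without CD163low replicate 2, and 4840 without monocyte replicate 1) and 6129 for Langerhans cells (without monocyte replicate 2). With only the 4 arrays compared in the fit, 5514 features passed for Langerhans cells.

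B cells were set against monocytes as the comparison within blood. The populations differed in 9077 features (20.9%), 4830 higher and 4247 lower in B cells. Among differences of 3 or more on the log2 scale the balance turned, with 603 higher and 877 lower. Feature 18424 rose most, by 9.14 ± 0.25 (SE, adjusted p = 1.32e-07). It was at 13.51 ± 0.14 (SD, n = 3) in B cells and below 4.57 in the other 4 populations. Feature 37614 rose by 7.83 ± 2.02 (adjusted p = 0.0196), with an SD of 4.98 between the 3 B cell arrays. It did not pass without B cell replicate 1 (adjusted p = 0.0588), B cell replicate 2 (0.0645), monocyte replicate 1 (0.107) or monocyte replicate 2 (0.0921), nor with only the 5 arrays compared in the fit (0.0675). Without B cell replicate 3 the difference was 10.71 (adjusted p = 1.7e-06), and with the replicate number as a block, which gives that array a term of its own, it was 10.71 too (adjusted p = 9.44e-06). Feature 838 fell by 10.07 on the log2 scale (SE 0.41, adjusted p = 9.99e-07), from 14.95 in monocytes to 4.88 in B cells. Feature 21605 fell by 9.87 (SE 0.43, adjusted p = 1.11e-06), from 15.60 to 5.73. The skin populations lay between 10.69 and 11.85 for these features. On B cell replicate 3, 93 features at least 16-fold higher in monocytes and in every skin population than on the other B cell arrays were higher by a median of 2.61 (log2). This comparison was added after the data were seen. Choosing features that are low on the other B cell arrays can by itself give part of the rise. Chosen likewise for replicates 1 and 2, 25 features each gave medians of −0.16 and −0.45, with reference arrays that include replicate 3. Without that array 8084 features passed (4225 higher, 3859 lower), and without monocyte replicate 1 the count was 4973.

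**Figure D3:**
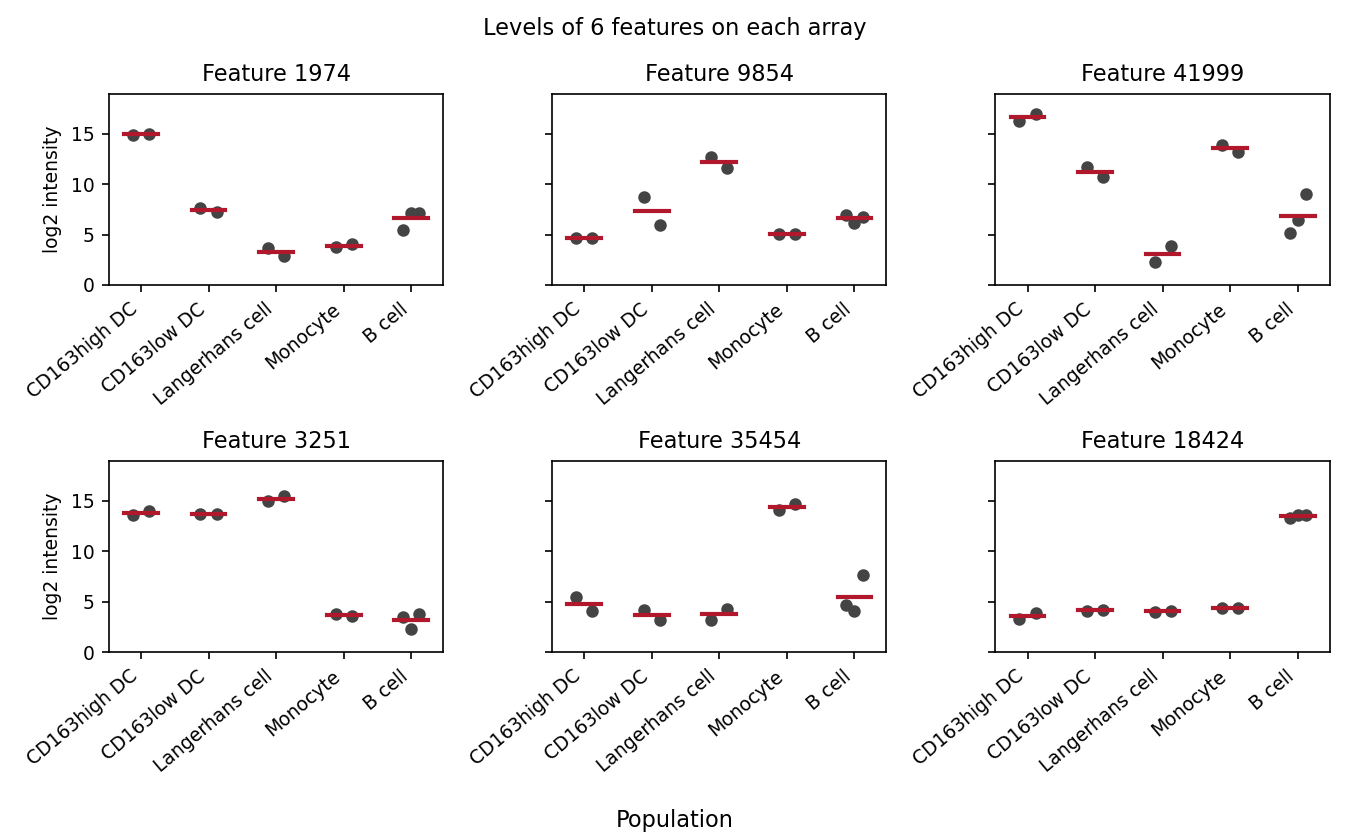
Log2 intensity (vertical axis) of 6 features on each of the 11 arrays (points) by population (horizontal axis), with the population mean as a red line. Feature 41999 runs from 3.07 in Langerhans cells to 16.63 in CD163high cells, while feature 3251 separates the skin from the blood and feature 18424 marks B cells.

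Features that marked one population were those higher than in each of the other 4, with an adjusted p of 0.05 and a log2 difference of at least 1 in all 4 tests. B cells had 1636 such features, CD163high cells 763, monocytes 711, Langerhans cells 373 and CD163low cells 101. These counts depend on the populations included, as a feature shared with a near population is not specific. The nearest populations to CD163low cells lay at root mean square log2 differences of 0.601 and 0.763, and the nearest to B cells at 1.11. For 67 features of CD163high cells and 3 of CD163low cells the smallest of the 4 differences was 4 or more on the log2 scale, with 11 in Langerhans cells, 59 in monocytes and 124 in B cells. The next highest population, taken by mean level with no minimum difference, differed between the sets. Where the other populations are all dim, as for B cell feature 18424 (at most 4.37), their order can rest on noise. No resemblance between populations is therefore read from these shares. Among the 373 Langerhans features CD163low cells came next in 191 (51.2%), and among the 711 monocyte features CD163high cells came next in 302 (42.5%) and B cells in 239 (33.6%). In the 763 features of CD163high cells, CD163low cells came next in 373 (48.9%) and monocytes in 220 (28.8%). In the 101 features of CD163low cells, CD163high cells came next in 37 (36.6%) and Langerhans cells in 35 (34.7%). Monocytes came next in 761 (46.5%) of the 1636 B cell features. Features lower than in all 4 others, by the same criteria, numbered 21 for CD163low cells, 117 for CD163high cells, 233 for Langerhans cells, 471 for monocytes and 1005 for B cells.

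The count for Langerhans cells was 804 without Langerhans replicate 2, 153 and 148 without CD163low replicate 1 and 2, and 184 with array weights. The count for CD163low cells was 40 with array weights, 41 without CD163high replicate 1, 60 without B cell replicate 2, and 64 and 67 without monocyte replicate 1 and 2. CD163high cells had 395 features without CD163high replicate 1 and 457 without CD163low replicate 2, and monocytes had 426 without CD163high replicate 2 and 452 without monocyte replicate 1.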

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

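The counts for each skin population against monocytes, the correlations of B cells, the 93 features on B cell replicate 3, and features 12235, 9269 and 6835, were added after the data were seen. No gene was named, so the gene list tests with their alternatives and the averaging of probes of a gene were not run. Repeating quantile normalisation or scaling to the 75th percentile moved no count by over 1.5 times; the columns were already alike, so neither tests the normalisation. Leaving out the dimmest 25% or 50% of features, a prior trend, a minimum difference of 1 and no minimum difference also kept every count within 1.5 times. Whether more features were higher or lower changed in 6 of 8 contrasts under some setting: 9 of 20 settings for CD163low cells against monocytes, 2 each for Langerhans against CD163high cells and skin cells against monocytes, and 1 each for CD163high cells, Langerhans cells and B cells against monocytes. Whether replicate numbers pair the arrays is not settled. Deviations of same-numbered arrays correlated at −0.168 (Langerhans and B cells, replicate 1) to 0.223 (CD163high and CD163low cells). The latter was the 1 of 10 pairs of populations over 0.1 for replicate 1. With 2 arrays in each population, replicate 2 gives the same value by construction. A shared source of same-numbered arrays therefore stays open for CD163high against CD163low cells. With the replicate block 3782 features differed between CD163high and CD163low cells and 1598 between Langerhans and CD163low cells, and no named feature crossed the threshold.

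Array weights, lowest for the Langerhans arrays (0.509 each), gave 766 features for Langerhans against CD163low cells, 4532 for Langerhans against CD163high cells, 184 specific to Langerhans cells and 40 specific to CD163low cells. With only the arrays compared in the fit, which leaves fewer degrees of freedom, 404, 3974 and 5514 features passed for Langerhans cells against CD163low cells, CD163high cells and monocytes. The share of higher calls against CD163low cells was then 22.5%, against 39.4%. Leaving out 1 array at a time gave 1217 to 4571 features for CD163high against CD163low cells, 768 to 2717 and 3666 to 7802 for Langerhans against CD163low and CD163high cells, 5382 to 10761 for skin cells against monocytes and 4973 to 10293 for B cells against monocytes. For CD163high, CD163low and Langerhans cells against monocytes the ranges were 3416 to 6726, 4636 to 8815 and 6129 to 10400. Specific features numbered 395 to 767 (CD163high), 41 to 132 (CD163low), 148 to 804 (Langerhans) and 426 to 746 (monocytes). The lowest of each range left a compared population with 1 array, which is then assumed to vary like the others. The highest count of each contrast given here came without a Langerhans array. In contrasts without Langerhans cells, the differences stay the same when such an array is left out. Only the shared estimate of the spread, with its degrees of freedom, could raise those counts. The cause of the other shifts was not tested.

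Spearman's correlation was 0.00988 for CD163high and CD163low cells, −0.0448 for CD163high cells and monocytes, −0.367 for CD163low cells and monocytes, and −0.160, 0.182 and −0.321 for Langerhans cells with CD163high cells, CD163low cells and monocytes. For B cells it was −0.330, −0.287 and −0.262 with CD163high, CD163low and Langerhans cells and −0.00833 with monocytes. The 50% brightest features gave −0.556 for CD163low cells and monocytes, and 0.358 and −0.498 for Langerhans cells with CD163low cells and monocytes, and −0.470 and −0.355 for B cells with CD163low and Langerhans cells. Leaving out 1 array gave −0.546 to −0.458 for CD163low cells and monocytes, and −0.294 to −0.210, 0.197 to 0.271 and −0.496 to −0.421 for Langerhans cells with CD163high cells, CD163low cells and monocytes. B cells gave −0.497 to −0.413, −0.451 to −0.388 and −0.363 to −0.288 with CD163high, CD163low and Langerhans cells, and −0.00671 to 0.0544 with monocytes. Feature 38944, which did not pass, ran from −11.70 to 0.34, the latter without CD163low replicate 2. No detection flag was used here, so how far dim signal limits the results is not known.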

Other observations

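All comparisons and tests in this part were chosen after the data were seen, and those on dim features of the Langerhans pair, on skin features that monocytes lack, on blood cells by direction and on sorted values also after their own result was seen. Differences between populations can be compared without a shared array, so that no common control adds to their correlation. Across features, the CD163high minus CD163low difference correlated with the monocyte minus Langerhans difference at r = 0.424 (covariance 0.507), and at 0.285 to 0.411 over 16 choices of single arrays. The 2 other ways of pairing these 4 populations gave lower values, 0.245 for CD163high minus Langerhans with monocyte minus CD163low (covariance 0.357) and 0.166 for CD163high minus monocyte with CD163low minus Langerhans (covariance 0.149). The first covariance is the sum of these 2 by construction, so they are not separate checks of it. The root mean square log2 difference, estimated from products of differences on separate arrays so that replicate noise drops out, was 0.601 between CD163low and Langerhans cells (0.588 to 0.614 over 2 choices of arrays). It was 0.763 between CD163low and CD163high cells (0.734 to 0.790), 1.05 between CD163high and Langerhans cells (1.05 to 1.06), 1.04 between CD163high cells and monocytes (1.03 to 1.05), 1.16 between CD163low cells and monocytes, and 1.26 between Langerhans cells and monocytes. For B cells it was 1.11 with monocytes (1.06 to 1.19 over 6 choices of arrays), 1.34 with CD163high, 1.24 with CD163low and 1.28 with Langerhans cells. Features are not independent replicates.

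CD163low cells lay part of the way from CD163high to Langerhans cells. Features with a difference of 2 or more (log2) between these on 1 replicate were measured on the other, where CD163low cells stood at 61.2% (4459 features) and 58.6% (3161 features) of the way. This place was not particular to them, as B cells stood at 49.3% and 60.8% and monocytes at 18.72% and 33.4%. On the axis from CD163low to CD163high cells, monocytes stood at 76.5% and 53.9%, B cells at 37.5% and 12.7%, and Langerhans cells at −8.75% and −24.2%. The monocyte position differed between features lower and higher in CD163high cells. Over features lower in CD163high than in CD163low cells, monocytes stood at 130.1% and 98.0%, and over features higher in CD163high cells at 40.3% and 23.7%. B cells stood at 103.1% and 75.05% over the lower features, near the monocytes, and at −6.76% and −29.9% over the higher ones. Over 225 features at least 16-fold higher in monocytes than in CD163low and Langerhans cells, the CD163high signal was 2.85% of the monocyte signal at the 25th percentile and 7.77% at the median. With the CD163low signal first subtracted from both, the share was 0.374% at the 25th and 15.6% at the 75th percentile, and at or below 0 in 38 features.

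The first pattern is a relative lean: set against each other, CD163high cells leaned toward monocytes and CD163low cells toward Langerhans cells. By root mean square difference CD163high cells were about as far from monocytes (1.04) as from Langerhans cells (1.05), and nearest to CD163low cells (0.763). The 2 populations differed more in their distance to Langerhans cells (1.05 against 0.601) than to monocytes (1.04 against 1.16). Shared behaviour of dim features would lose the correlation in bright ones, but it was 0.475 in the 50% brightest features (0.336 to 0.494 over single arrays). A difference common to blood cells would cancel in monocytes minus B cells, where r fell to 0.257 (0.190 to 0.234 over single arrays) but not to 0. For features higher in CD163high cells it is argued against as the whole cause (ratio of B cell to monocyte position at most −0.168). A part shared by blood cells could be hidden there, as B cells are the only other blood population and of another lineage. For the lower features a common difference stays open (ratio at least 0.766), and features that simply mark CD163low and Langerhans cells would give the same. A fixed share of monocyte RNA in the CD163high samples is argued against as the whole cause, though part of r could come from it. Here the signal of 1 monocyte array was removed and r measured on the other, so r started at 0.414 and not at 0.424. With 2.85% of the monocyte signal removed r was 0.345 (0.217 to 0.360 over single arrays), and with 7.77% it was 0.254 (0.126 to 0.295). The spread of the share after subtraction (75th to 25th percentile ratio 41.7) decides nothing, as many of its values lay at or below 0. Other mixing, such as between the Langerhans and CD163low samples, was not tested for this pattern and stays open. What the lean reflects in the cells was not tested, as no gene is named and the gate behind the CD163high arrays is open.

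The second pattern is the spread between the Langerhans arrays, whose difference had a median absolute deviation of 0.714 (log2) against 0.490 in the next most variable pair, the monocytes. Noise of dim features cannot be told apart: the spread was 1.08 times the highest of the other pairs in the brightest of 5 equal sets of features, but from the dimmest set upward it was 1.21, 1.51, 1.76 and 1.29 times, so the excess was not largest where signal was dimmest. Uneven signal over the array surface cannot be told apart either: subtracting the median of the 40 nearest feature numbers removed 21.7% of the excess variance, and the layout of the array was not used. Different animals or pools behind these arrays stay open and were not tested.

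The third pattern is B cell replicate 3, which correlated with monocytes at 0.930 against 0.907 and 0.910 for replicates 1 and 2. This was not particular to monocytes. In the same order r was 0.901, 0.875 and 0.881 with CD163high cells, 0.912, 0.889 and 0.895 with CD163low cells, and 0.897, 0.877 and 0.881 with Langerhans cells. Monocyte features (173, at least 16-fold above the other B cell arrays and 4-fold above skin cells) were higher on replicate 3 by a median of 1.35 (log2), against −0.165 for replicate 1 minus 2. Tested likewise, replicates 1 and 2 gave −0.69 and −0.51, and −0.16 and −0.45 for features high in monocytes and skin cells. The reference arrays of these 2 replicates include replicate 3, here and for the B cell features below. Skin cell features were higher on replicate 3 too, by 0.99. Monocyte RNA therefore cannot be told apart from RNA of other cells: 48 skin features that monocytes lack were higher by 0.27, with quartiles of −0.09 and 1.64. A narrower signal range would raise all features that are dim in B cells, but 1758 features as dim on the other B cell arrays and no higher in other populations (within 1 on the log2 scale) differed by a median of −0.14 (quartiles −0.35 and 0.07) against 2.61 (1.88 and 3.28) for those high in monocytes and skin cells, which argues against it for this rise; the fall of B cell features (median −0.24; replicates 1 and 2: −0.08 and 0.12) stays open, and sorted values within 0.0409 decide nothing, as normalisation sets them. No biological explanation was tested, since the labels separate the B cell arrays only by number.

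Single features differed between replicate arrays by 6 or more on the log2 scale in 4 cases for CD163high cells, 9 for CD163low cells, 9 for Langerhans cells, 3 for monocytes and 5 for B cells, with the largest difference, 14.21, in CD163high cells.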
